A study of Hydra vulgaris with 6 samples.

How the data were processed

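The data were ChIP-seq libraries from complete polyps of Hydra vulgaris, with 2 files each for input, histone H3 and Pol II. Per the labels, nuclei were sonicated, complexes were isolated with antibody, and libraries were read on a SOLiD sequencer. The authors deposited 1 list of aligned reads per sample, each row giving the scaffold, start, end, name, score and strand of a read. The score column that the authors deposited was 0 in every row and held no measurement. Bowtie and bedtools are named in the submitters' processing notes, without version or settings. The genome build, alignment filters and treatment of repeated or multiply mapping reads are not given in the sources used here. Coordinates are those of the deposited files, written from 1, on scaffolds of an unstated build. No sequence or annotation of that build was used here, so windows carry no gene, exon or intron, and GC content was not examined.

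Reads were tallied by 5′ end in full-length 5 kb windows, and windows with a mean of at least 10 reads over the 6 files were tested. The comparisons, the test and the rule for naming windows were fixed before the data were examined. The planned test was limma-voom (limma 3.58.1, R 4.3.3) with all 6 files in 1 fit, scaling by the trimmed mean of M values over 10 kb bins (30% of M and 5% of A trimmed) and Benjamini-Hochberg adjustment at 0.05. The naming rule took, for Pol II and for H3 against input, the 10 highest and 5 lowest windows by log2 fold among those past the threshold with both files on the same side of both input files. Nothing in the labels says that replicates came from separate cultures.

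The files of a group shared read positions as runs of 1 library would, so the main values given here were chosen after seeing the data. Both files of a group were merged, each scaffold, 5′ end and strand was counted once, and the libraries were compared by a two-sided exact binomial test with Benjamini-Hochberg adjustment at 0.05 (Python 3.11.15, scipy 1.17.1, statsmodels 0.14.6). Folds were scaled by the trimmed mean of M values over the merged positions, and intervals are 95% Clopper-Pearson intervals turned into folds. Log2 folds that set the 2-fold and 4-fold classes had 0.5 added to each count. Median distinct positions per tested window were 57 for input, 29 for H3 and 40 for Pol II. Reads carry no molecular identifiers, and counting a position once loses molecules where reads are dense, so the H3 folds of the lowest named windows are given also on deposited reads, and Pol II regions were checked on them. For profiles, regions were called on 1 random part of the molecules, 0.5 of them, and measured on the rest, with 200 bootstrap draws. In the correlation of Pol II and H3 folds and in the classes of windows by Pol II, the 2 folds used separate parts of the input. Elsewhere both folds of a window or region shared 1 input. Picking windows for a high Pol II fold favours low input counts, which raises the H3 fold.

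Both tests were tested on simulated data with 200 of 111169 windows changed, for Pol II against input. The exact test called 100% of 4-fold higher, 46% of 2-fold higher, 6% of 2-fold lower and 60% of 4-fold lower windows, and 0.0036% of unchanged ones. The limma-voom fit called 100%, 80%, 34% and 86%, and 0.0081% of unchanged ones. Its simulated files were independent, without the repeated reads and shared positions of the real files. The rates of this fit therefore do not carry over to the real files, where it called 15.3% of windows between 2 random parts of the Pol II library. By the exact test, most 2-fold lower windows were not detectable at this depth.

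Alternatives fixed beforehand were scaling by total reads and by median of ratios, a mean of at least 20 or 1 reads, 1 read per position in each file, the replicate number as a block, limma-trend, 2 kb and 10 kb windows, windows without high-copy sequence and each file left out. Planned results on promoters, gene bodies, gene lists, gene starts and across genes were not run, because they need an annotation of the build of the files.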

Results

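Chromatin immunoprecipitation followed by sequencing was carried out on complete polyps of Hydra vulgaris, strain Ind-Pune, a freshwater cnidarian. Chromatin was recovered with an antibody to RNA polymerase II (Pol II, the enzyme that transcribes protein-coding genes) or with an antibody to histone H3 (a core protein of the nucleosome), and DNA taken without antibody served as input. The labels list 2 replicates for each of the 3 groups. The input files held 4690745 and 4511579 aligned reads, the H3 files 3061978 and 2819153, and the Pol II files 6086172 and 5885035. Every read spanned 38 bases, and reads fell on 7662 scaffolds with an observed span of 713 Mb.

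The 2 files of each group behaved as 1 library read in 2 runs and were counted as 1 sample, so n = 1 for each group and no comparison has a replicate error. Of the read positions (scaffold, 5′ end and strand) in an input file, 20.7% and 21.4% recurred in the other input file. The share was 34.2% and 36.6% between the H3 files, and 57.9% and 59.2% between the Pol II files. Between files of different groups it was 1.10% to 2.31%. Read counts of the 2 files over 5 kb windows differed by about the sampling noise, with a chi-square per degree of freedom of 1.005 for input (p = 0.111), 1.009 for H3 (p = 0.0287) and 1.004 for Pol II (p = 0.191). Between groups the same ratio was 1.85 to 3.34. Repeated reads were most frequent in Pol II, with 2.40 reads per distinct position in the merged files against 1.56 for H3 and 1.28 for input. Values below are therefore counts of distinct positions over both files of a group, 4980752 for Pol II, 3761385 for H3 and 7183719 for input, given as a fold over input with a 95% exact interval. These intervals cover counting error only, folds are relative to the average of each library, and each test compares these libraries and not conditions.

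**Figure D1:**
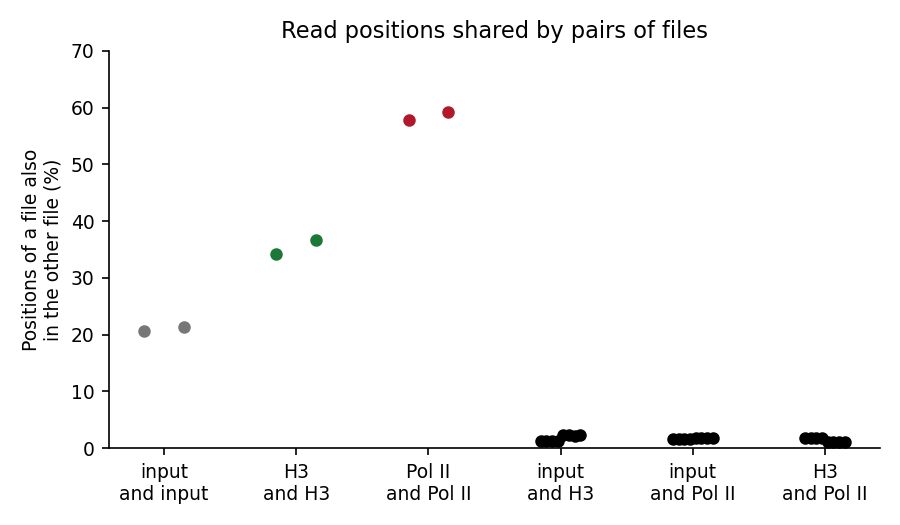
Percent of the read positions of a file (vertical axis) that also occur in another file, for each pair of groups (horizontal axis); each point is 1 file of a pair. Pairs within a group lie between 20.7% and 59.2%, and pairs between groups between 1.10% and 2.31%.

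The first comparison asked where Pol II lay on the genome relative to input. Of 111169 tested windows of 5 kb, 690 had more Pol II positions than input and 409 had fewer, beyond counting error (exact binomial test, Benjamini-Hochberg adjusted p under 0.05). At least a 2-fold excess was seen in 443 windows and a 4-fold excess in 38, against 169 windows at least 2-fold lower and 4 at least 4-fold lower. The highest window, NW_004172322.1 from 40001 to 45000, had a Pol II fold of 13.2 (interval 9.74 to 18.2), from 432 Pol II and 47 input positions. NW_004168944.1 from 95001 to 100000 reached 11.6-fold (8.55 to 16.1), NW_004166870.1 from 540001 to 545000 reached 9.32-fold (7.62 to 11.5) and NW_004171884.1 from 45001 to 50000 reached 9.14-fold (7.19 to 11.8). H3 in these 4 windows was 0.978, 0.856, 0.940 and 0.908 times input, with 1 inside each interval. Both folds share the input positions by which the windows were picked, which favours a higher H3 fold. NW_004171118.1 from 55001 to 60000 was 10.6-fold higher (5.80 to 21.4) on 12 input positions, NW_004166890.1 from 60001 to 65000 was 8.29-fold higher (5.93 to 11.9) and NW_004167159.1 from 45001 to 50000 was 7.42-fold higher (5.39 to 10.4). A further 3 windows of the naming rule, NW_004170545.1 from 1 to 5000 at 6.99-fold, NW_004167903.1 from 50001 to 55000 at 6.10-fold and NW_004168069.1 from 25001 to 30000 at 5.38-fold, rested on 8, 4 and 4 input positions. Of the 10 highest windows of that rule, 9 passed the exact test and NW_004168069.1 did not. H3 and Pol II reads enter the minimum mean, so windows with few input reads passed it more readily where these were high. All 5 input reads of NW_004167903.1 from 50001 to 55000 lay in input replicate 1, and its limma-voom log2 fold for Pol II went from 3.11 to 4.81 without that file and to 1.41 without input replicate 2, where the call was lost (adjusted p = 0.191), so its size rests on 1 input file.

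**Figure D2:**
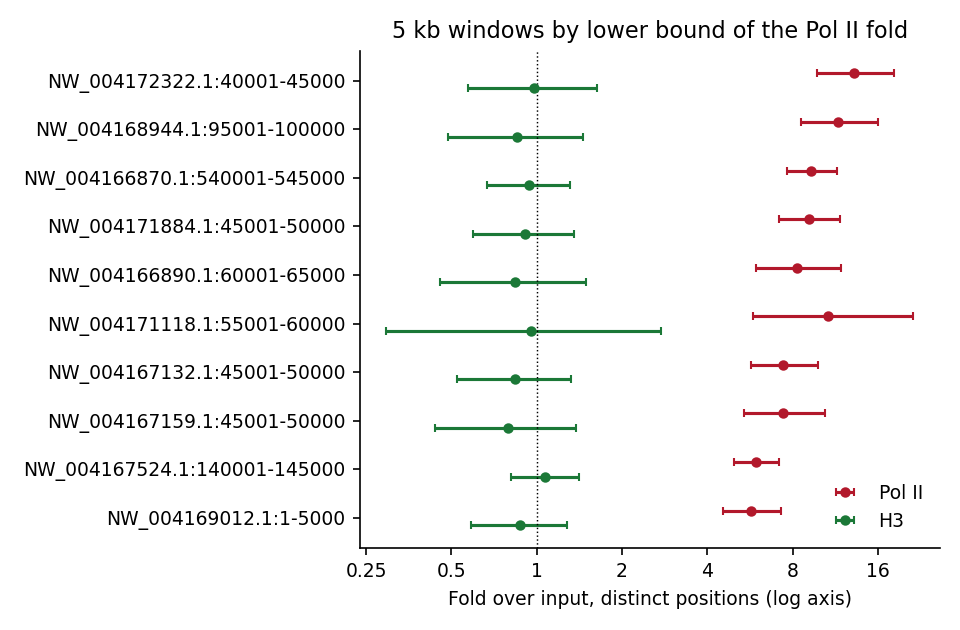
Fold over input of distinct positions (log horizontal axis) for Pol II and H3 in the 10 windows of 5 kb with the highest lower bound of the Pol II fold (vertical axis); points are 1 library each and bars are 95% exact intervals for counting error. Pol II ranges from 5.72 to 13.2, and every H3 interval includes 1. Both folds share the input positions by which the windows were picked, which favours a higher H3 fold.

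The lowest Pol II windows of the naming rule were NW_004167106.1 from 220001 to 225000 at 0.127 times input (0.0249 to 0.402, 3 Pol II and 34 input positions), NW_004167376.1 from 190001 to 195000 at 0.253 (0.0869 to 0.610), NW_004168348.1 from 75001 to 80000 at 0.272 (0.129 to 0.523), NW_004169638.1 from 65001 to 70000 at 0.287 (0.0976 to 0.701) and NW_004169264.1 from 25001 to 30000 at 0.319 (0.143 to 0.642). Of these 5, only NW_004167106.1 and NW_004168348.1 passed the exact test. All 5 kept their limma-voom call when 1 file was left out, but 3 of them moved by more than 1.5 times. NW_004169638.1, with 1 and 8 Pol II reads in the 2 files, went from a log2 fold of -2.88 to -1.61 without Pol II replicate 1 (adjusted p = 0.0496) and to -4.16 without Pol II replicate 2. NW_004167376.1 went from -2.81 to -3.48 and -2.14, and NW_004168348.1 from -2.69 to -3.35 and -2.05. Across all tested windows the spread of the Pol II fold beyond counting error had an SD of 0.25 on the log2 scale, a factor of 1.19. On folds that include counting error, which reduces r, neighbouring windows had a Pearson r of 0.115 at 5 kb and 0.0650 at 10 kb (across windows, which are not independent replicates). The planned limma-voom test on the reads of the 2 files called 17771 windows (9089 higher, 8682 lower). It measures only the spread between runs of 1 library, and it called 15407 of 100768 windows when the molecules of the Pol II library alone were split at random into 2 equal parts. Its count was 7846 (3149 higher, 4697 lower) and 8290 (3409 higher, 4881 lower) without input replicate 1 and 2, and 9963 (6015 higher, 3948 lower) and 9966 (6066 higher, 3900 lower) without Pol II replicate 1 and 2. With scaling by total reads 8444 were higher and 9324 lower, so which direction had more windows depended on the scaling and on the files used. Replicate 1 files alone gave 360 windows by the exact test and replicate 2 files alone gave 333. In 10 kb windows 197 were at least 2-fold higher and 40 at least 2-fold lower by the exact test.

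Windows of 1 kb were tested by the exact test where the 3 groups had a mean of at least 10 distinct positions, which left 217656. Pol II counts enter that mean, so kilobases with few input positions passed it more readily where Pol II was high. Of those tested, 436 were at least 2-fold higher in Pol II and 157 at least 2-fold lower. Joined across gaps of up to 1 kb, the higher ones formed 278 regions on 242 scaffolds. Of these, 202 were single windows, 48 were at least 3 kb long and 13 at least 5 kb. On deposited reads 266 of the 278 were at least 2-fold higher and 12 were not, among them NW_004173276.1 from 37001 to 40000, at 2.32-fold on distinct positions and 1.57-fold on deposited reads, and NW_004174194.1 from 31001 to 32000, at 2.09-fold and 0.994-fold. The 278 held 0.553% of the Pol II positions and 0.132% of the input positions. The longest, NW_004167159.1 from 40001 to 49000, was 6.57-fold higher in Pol II (5.26 to 8.29) and 0.878 times input in H3 (0.600 to 1.27). NW_004169695.1 from 15001 to 22000 was 5.19-fold higher in Pol II (4.19 to 6.47), and H3 was also higher there, at 1.97-fold (1.499 to 2.58). NW_004171903.1 from 28001 to 35000 was 5.50-fold higher in Pol II (4.35 to 7.01) with H3 at 1.02 (0.704 to 1.47).

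**Figure D3:**
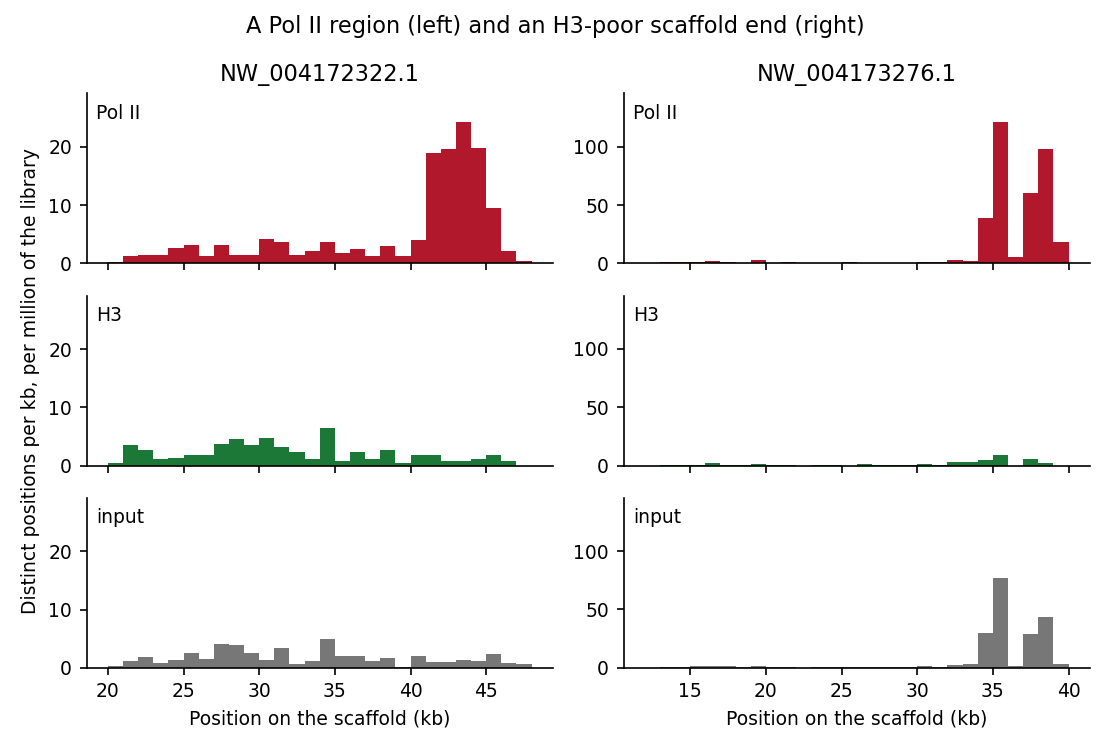
Distinct positions per kb, divided by the number of distinct positions of the library, as on the axis label (vertical axes, 1 scale per scaffold), along NW_004172322.1 and NW_004173276.1 (horizontal axes in kb); each bar is 1 kb of 1 library. On the left Pol II rises from 41001 to 46000 without a rise in H3 or input, and on the right input and Pol II rise much more than H3 between 34001 and 39000, except in the kilobase from 36001.

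Around Pol II regions called on 1 set of molecules, folds were measured on the remaining molecules. The summit is the centre of the summit kilobase. Pol II was 3.57-fold higher (bootstrap interval over 94 regions 3.11 to 4.08) within 500 bp of the summit, 2.27 (1.96 to 2.59) at 1 to 3 kb and 1.21 (1.11 to 1.34) at 5 to 10 kb. H3 was 0.853 times input (0.656 to 1.02) at the summit, 0.817 (0.665 to 0.961) at 1 to 3 kb and 1.03 (0.962 to 1.09) at 5 to 10 kb. After leaving out regions within 10 kb of a kilobase with over 5 times the median input, a choice made after this H3 profile had been seen, 59 regions remained. Their H3 fold at 1 to 3 kb was 0.928 with an interval of 0.854 to 1.004, and their Pol II fold was 4.81 (3.84 to 5.88) at the summit and 1.092 (0.986 to 1.25) at 5 to 10 kb, where the interval then included 1.

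**Figure D4:**
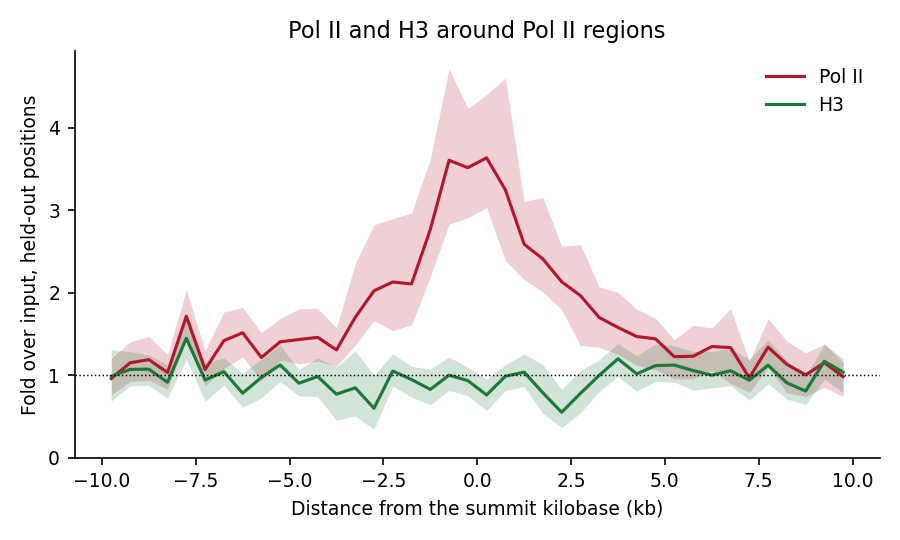
Fold over input (vertical axis) of held-out distinct positions in 500 bp bins by distance from the centre of the summit kilobase in kb (horizontal axis), pooled over 94 Pol II regions. Lines are the libraries and bands are 95% bootstrap intervals over regions. Pol II is 3.57-fold higher within 500 bp of the summit and 1.21-fold higher at 5 to 10 kb (1.092-fold, with an interval including 1, without regions near high-copy sequence), while H3 is 0.853 and 1.03 times input.

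The comparison of H3 with input asked where nucleosome density departed from the average. Fewer windows departed from input in H3 than in Pol II, on fewer positions, while the spread beyond counting error was similar in size, with an SD of 0.21 on the log2 scale for H3 and 0.25 for Pol II. Of the 111169 windows, 91 were higher and 17 lower in H3 beyond counting error, of which 40 were at least 2-fold higher and all 17 at least 2-fold lower. Leaving out the 166 windows with over 5 times the median input left 58 higher and 8 lower. The adjustment was repeated on the rest, and some of the lower windows that lost their call were not among those left out. In 164 of these 166 windows the median H3 log2 fold was 0.24 on distinct positions and 0.011 on deposited reads. Counting each position once thus raised H3 folds in dense windows, and some of the 91 higher calls may rest on it. The 40 windows at least 2-fold higher stood at 1.80 to 5.56 on deposited reads. Detection of H3 losses was not simulated. Replicate 1 files alone gave 41 windows and replicate 2 files alone gave 49. By the naming rule the lowest windows were led by NW_004173276.1 from 35001 to 40000, with an H3 fold of 0.107 (0.0817 to 0.139) on 1107 input positions, 19.4 times the median window, and of 0.0298 on deposited reads. NW_004171935.1 from 10001 to 15000 stood at 0.183 (0.099997 to 0.311), NW_004170333.1 from 5001 to 10000 at 0.188 (0.109 to 0.306), NW_004170809.1 from 5001 to 10000 at 0.239 (0.0737 to 0.606) and NW_004173805.1 from 1 to 5000 at 0.242 (0.124 to 0.432). On deposited reads the H3 folds of these 4 were lower, at 0.0630, 0.0666, 0.0548 and 0.0884. NW_004173805.1, with 3 and 10 H3 reads in the 2 files, had a limma-voom log2 fold of -2.73 without H3 replicate 1 and -4.43 without H3 replicate 2. All of these 5 passed the exact test except NW_004170809.1, with 5 H3 on 40 input positions. The 10 highest windows of the naming rule had 4 to 13 input positions each. Such windows could pass the minimum mean through their H3 and Pol II reads, so this filter favoured high folds at low input. Taken singly, 9 of the 10 had an interval above 1, but only 1, NW_004168094.1 from 40001 to 45000 at 5.27-fold (2.26 to 13.7), passed the exact test over all windows. Of these 10, 9 lost their limma-voom call when 1 input or H3 file was left out, while none of the 5 lowest did. NW_004168094.1 was among the 9, with a log2 fold of 2.46 that fell to 1.98 without input replicate 1 (adjusted p = 0.0672). The highest folds, which did not pass, were NW_004167903.1 from 50001 to 55000 at 7.66-fold (2.47 to 31.5) on 4 input positions and NW_004168200.1 from 5001 to 10000 at 6.13-fold (2.14 to 21.4) on 5. The limma-voom log2 fold of H3 in NW_004167903.1 was 5.10 without input replicate 1, which held all of its input reads, and 1.69 without input replicate 2, where the call was lost (adjusted p = 0.184). That of NW_004168200.1 went from 2.98 to 3.75 and 2.22, and its call was lost without input replicate 2 (adjusted p = 0.0866). NW_004167708.1 from 115001 to 120000, at 2.68-fold (0.732 to 10.7), had an interval that included 1. Outside the rule, and picked after its values were seen, NW_004168434.1 from 55001 to 60000 had the highest lower bound, at 4.23-fold (3.18 to 5.69) on 71 input positions, and passed. The planned limma-voom test called 6303 windows for H3 (3778 higher, 2525 lower). Its count fell to between 2187 and 2463 when an H3 or an input file was left out, with 1170 higher and 1183 lower without input replicate 1, and 1696 higher and 491 lower without H3 replicate 1.

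Set against each other, Pol II and H3 differed in more windows than either did from input. Pol II exceeded H3 beyond counting error in 1663 windows and lay below it in 2194, of which 1460 and 1369 differed at least 2-fold. Which of these 2 counts was larger depended on window size and depth, with 1099 higher and 1804 lower in 2 kb windows, 633 and 449 in 10 kb windows, 597 and 734 in replicate 1 files alone, and 492 and 661 in replicate 2 files alone. Replicate 1 files alone gave 1439 windows in all and replicate 2 files alone gave 1237. The limma-voom test called 29350 windows (14014 higher, 15336 lower). It called 14951 (5350 higher, 9601 lower) without H3 replicate 1 and 15998 (5983 higher, 10015 lower) without H3 replicate 2, and without Pol II replicate 1 the higher windows were more (11188 higher, 10451 lower). The spread of the Pol II to H3 fold beyond counting error was 0.40 on the log2 scale.

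H3 was then measured in windows classed by Pol II, using 1 random part of the input positions for the class and the other part for the H3 fold. Windows of a class also had to pass the exact test for Pol II against the first part. In 43 windows at least 4-fold higher in Pol II, H3 was 1.02 times input (bootstrap interval over windows 0.937 to 1.10). In 271 windows at least 2-fold higher, H3 was 0.969 (0.932 to 1.01), and with the input parts exchanged it was 0.907 (0.814 to 0.981) in 281 windows, so whether 1 lies inside the interval depended on the part used. In 112 windows at least 2-fold lower in Pol II, H3 was 1.14 times input (1.09 to 1.18), and 1.13 (1.08 to 1.19) with the parts exchanged. By fold alone, without the test, 102 windows were at least 4-fold higher, 2546 were 2-fold to 4-fold higher and 1302 at least 2-fold lower. Their median H3 log2 folds were -0.063 (bootstrap interval -0.228 to -0.013), -0.063 (-0.123 to -0.063) and 0.169 (0.137 to 0.206). After scaling, -0.063 is the value of a window with equal H3 and input counts. Median input counts in the part used were 12, 15 and 21, so log2 folds took few separate values and these intervals are coarse. Their pooled H3 folds were 0.983, 0.939 and 1.13.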

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

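Every comparison on distinct positions, and each of its alternatives, was chosen after seeing the data; the limma-voom alternatives were chosen before the data were examined. For limma-voom, limma-trend gave 8042 windows for Pol II against input, and 10 kb windows gave 11402 for Pol II against input and 18734 for Pol II against H3, with fewer windows tested. Leaving out a file gave 7846 to 17504 windows for Pol II against input, 2187 to 6393 for H3 against input and 14951 to 29274 for Pol II against H3, where the lone file of a group is assumed to vary like the others. The replicate number as a block gave 17023, 7627 and 30288. Files of the same number did not deviate together (correlations of -0.0005, -0.0004 and 0.0021). As the files of a group differ by about sampling noise alone, these correlations cannot show whether the numbers pair the files. The share of H3 calls that were higher was 81.6% in 2 kb windows and 44.8% by limma-trend, against 59.9%. In the 15 named windows for Pol II, 1 of 198 alternative values lost the call, without input replicate 2. In the 15 for H3, 11 of 187 lost it, all when an input or H3 file was left out. These belong to 9 of the 10 highest windows, so most of the highest H3 calls need both files, and none of the 5 lowest lost its call. None changed direction. Of these 30 entries, 15 fell below the minimum count with 1 read per position in each file and 17 with a mean of at least 20 reads, so they have no value there.

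On distinct positions, 1 file of each library alone gave 333 to 360 windows for Pol II against input, 41 to 49 for H3 and 1237 to 1439 for Pol II against H3, having fewer positions. At least 2-fold higher were 220 to 237, 17 to 21 and 492 to 597, and at least 2-fold lower 64 to 76, 9 to 9 and 661 to 734. In 10 kb windows H3 gave 163 windows, at least 2-fold higher were 197 for Pol II against input and 633 for Pol II against H3, and at least 2-fold lower were 40 and 449. Without high-copy windows, and with the adjustment repeated on the rest, H3 gave 66, of which 8 were at least 2-fold lower. For Pol II against H3, windows at least 2-fold lower outnumbered those at least 2-fold higher in 2 kb windows (1804 and 1099) and in 1 file of each library alone, the reverse of 5 kb and 10 kb windows. The cause of the changes with window size was not tested. Without regions near high-copy windows, 199 of 278 Pol II regions were left (266 were also at least 2-fold higher on deposited reads), and the Pol II fold was 4.81 within 500 bp of the summit and 1.092 (0.986 to 1.25) at 5 to 10 kb, so the interval there no longer lay above 1. The H3 fold in windows at least 2-fold higher in Pol II was 0.907 with the input parts exchanged, and 0.951 with high-copy windows also left out. The correlation of Pol II and H3 folds was -0.12 with the input in 2 separate parts, -0.102 with 3 and reversed to 0.0996 with the same input for both, which adds a shared counting error by construction. Depth limits the detection of 2-fold losses in particular. No planned result on promoters, gene bodies, gene lists, gene starts or across genes was run.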

Other observations

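Of the tests in this part, the split by input density was written before its result was seen; the others were chosen after the result was seen.

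limma-voom called 17771 windows for Pol II and 6303 for H3 against input. Amplified copies of the same molecules, present in both files of a group, may account for much of the Pol II count, since 2 equal parts of the molecules of the Pol II library alone were called in 15.3% of windows, against 15.99% for Pol II against input. For H3 the same split gave 0.0908%, against 5.67%. It had 0.5 times the depth of the comparison and 13.9% of its windows had an unadjusted p under 0.05, so the part played by copies in the H3 count cannot be told apart from real differences. No biological explanation was tested.

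At 2 scaffold ends H3 was low relative to a dense input. These stretches were picked by their H3 values. Each runs from the first to the last kilobase whose H3 fold had an upper bound under 0.25. NW_004173276.1 from 34001 to 39000 had an H3 fold of 0.116 (0.0914 to 0.146) at 96.1 times the median input reads per kb. NW_004174194.1 from 30001 to 33000 had 0.0799 (0.0513 to 0.119) at 70.3 times. The rest of each scaffold stood at 0.817 (0.642 to 1.03) and 0.580 (0.255 to 1.21), the latter on 10 H3 and 33 input positions. The rest of NW_004173276.1 includes the kilobase from 39001, with 0 H3 on 23 input positions. Per kb, H3 positions were still more frequent at the ends (79 in 5 kb and 25 in 3 kb) than in the rest (102 in 35 kb and 10 in 30 kb). High copy number alone is argued against by the other 164 windows above 5 times the median input, whose median H3 log2 fold on deposited reads was 0.0114 (-0.0623 to 0.0456) with 3 below -1, and by 46 kilobases elsewhere above 40 times the median, with a median on deposited reads of 0.36 (0.02 to 0.76) and 1 below -1. On distinct positions, as for the folds at the ends, these medians were 0.24 (0.19 to 0.27) and 0.66 (0.51 to 0.81). Low H3 in dense input was not limited to the 2 ends. Among the 3 windows below -1 were NW_004171935.1 from 10001 to 15000 and NW_004170333.1 from 5001 to 10000. They lay 10 and 5 kb from the nearer observed scaffold end, with H3 folds of 0.0630 and 0.0666 on deposited reads. Loss of molecules on counting a position once is argued against by the deposited reads, on which the higher of the H3 folds at the 2 ends was 0.0315. The Pol II folds of 1.78 and 1.83 there were 1.053 and 1.168 on deposited reads, so much of that excess depended on counting each position once. It did not do so evenly. On deposited reads the Pol II region of NW_004173276.1 from 37001 to 40000 stayed at 1.57-fold, and that of NW_004174194.1 from 31001 to 32000 was 0.994-fold. DNA without nucleosomes, such as organelle or bacterial sequence, stays open, as no sequence of these scaffolds was examined.

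Pol II and H3 folds ran weakly against each other across windows (Pearson r = -0.123, across windows, which are not independent replicates). With the same input for both, r was 0.0996 and the covariance 0.0172, against 0.373 and 0.0438 for simulated unchanged libraries sharing that input. Noise of a shared input adds a positive covariance, and r was measured on separate parts of the input. A trend with input density is argued against by a mean r of -0.11 within 10 classes of windows by density. Sequence composition and amplification that differ between the libraries were not tested and stay open. No biological explanation was tested. In the 43 windows past the exact test and at least 4-fold higher in Pol II, H3 was 1.02 times input, with an interval of 0.937 to 1.10 that includes 1. In all 102 windows at least 4-fold higher, past the test or not, the pooled H3 fold was 0.983. Their median H3 log2 fold was -0.063 (bootstrap interval -0.228 to -0.013). After scaling, -0.063 is the value of a window with equal H3 and input counts in the part used. With a median of 12 input positions in that part, log2 folds took few separate values. The interval therefore cannot show whether H3 was lower there.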
